A study of Mus musculus with 179 samples.

How the data were processed

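RNA was measured in 179 single cells from mouse pancreatic acinar organoids after 9 days of culture, each deposited as a sample of its own, by Smart-seq3 within a protocol that also profiles DNA methylation and chromatin accessibility. Methylation and accessibility were not analysed here. The authors deposited a table of UMI counts and a table of read counts, each with a row per cell and 32100 Ensembl gene identifiers, both as raw whole numbers with no normalization. STAR and featureCounts and the builds GRCm38 and mm10 are named, with no versions, per the submitters' processing notes. How UMIs were collapsed, how cells and genes were chosen and which reads were counted is not given in the sources used here.

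Rows were matched to samples by name. Of the identifiers, 31985 had a symbol and 115 did not (0.0932% of UMIs), and 22 shared a symbol with a more abundant identifier and kept their own. Gene positions are those of GRCm38. No value had more UMIs than reads, and 142295 values had reads and no UMI (0.332% of reads).

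All cells form 1 group with no animal, donor or culture named, so a cell is not a replicate and no test, p-value or standard error was computed from cells. Cells with at least 1000 UMIs were analysed, which kept all of them, with no limit on mitochondrial UMIs. No doublet caller was run, because each sample is a single cell per the labels; 2 cells in 1 well are weighed in the closing observations. List levels are CPM of pooled UMIs with exact 95% Poisson intervals. Shares are of cells with at least 3 genes of a list (1 for single genes) after thinning each cell to 40000 UMIs, which kept 161 cells and left out 18, with exact 95% binomial intervals; a count of 0 was taken to allow 3 counts. All intervals cover counting error only. Variable genes were ranked by the squared coefficient of variation beyond the Poisson part, relative to the running median of 100 genes of like mean, for genes with a mean of at least 0.5 UMI per cell. Clusters came from the Leiden method at resolution 0.5 on 10 nearest neighbours, 15 principal components and 1500 variable genes, without mitochondrial genes. Cluster genes were ranked by fold over the other cells with 5 CPM added, among genes with at least 50 UMIs in the cluster.

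The named genes are the 15 most abundant nuclear genes other than ribosomal protein genes, the 20 most variable genes, the 4 highest members of each list and any needed as not detected, the 5 leading genes of each cluster, the 5 genes with the highest and the 5 with the lowest reads per UMI among genes with at least 200 UMIs, and Ptf1a, Bhlha15, Sox9, Krt19, Pdx1, Mki67 and Stmn1. A few genes that this rule names are not reported here. Lists, cell filter, rules and most of the other settings tried were set before the data were examined.

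Some choices came later. The first estimator of excess variation recovered few simulated genes and was replaced by a depth-weighted one after its list of 20 genes had been seen. The new one recovered 100 of 100 genes simulated with 10 times and 100 of 100 with 30 times the common excess, over 13394 genes. The simulated excess was spread over all cells, whereas the 20 leading genes of the data had most of their UMIs in 1 cell. The simulation therefore does not cover genes of that kind. The cluster search was run until stable, which had not been specified, and 2 rounds were added as an alternative. On simulated cells with no groups over 13394 genes the clustering returned 4 clusters. With 60 cells in which 200 genes were 4 times higher it returned 3, with an adjusted Rand index of 0.746 to the simulated groups. The levels of 1000 CPM that single out cells, and the alternatives without the 1 or 2 cells richest in enzymes, without the fibroblast-rich cells and with at least 5000 genes, were also chosen after seeing the data.

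Those other settings covered reads in place of UMIs, other cell filters, equal weight per cell, other totals, title numbers up to 96 or from 97, other thinning and detection rules, size factors of scran, and other cluster settings. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3 with scran 1.30.0.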

Results

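The data describe single cells of 1 group from mouse exocrine pancreas, each deposited as a sample of its own and named Acinar followed by a number. Acinar cells, the cells that make and secrete digestive enzymes, were isolated from wild-type C57BL6 mice by tissue digestion and a density gradient. They were then grown for 9 days as organoids embedded in Matrigel, a basement membrane gel. RNA was measured in each cell with Smart-seq3, a plate-based method that reads full-length transcripts and counts molecules through unique molecular identifiers (UMIs), as the RNA part of a protocol that also reads DNA methylation and chromatin accessibility in the same cells. No animal or culture was named for any cell, and cells of 1 group are not replicates. The values below therefore describe this population, with no test and no p-value, and their intervals cover counting error only. Levels are the CPM of pooled UMIs with exact 95% Poisson intervals, shares of cells have exact 95% binomial intervals, and the gene lists were fixed before the data were examined.

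Each cell gave a median of 165267 UMIs (quartiles 110635 and 208344, range 3258 to 329522) and 362296 reads (range 4691 to 929032). A median of 11582 genes per cell had a UMI (range 1826 to 13687). Mitochondrial genes held a median of 1.01% of UMIs and at most 36.6%, and ribosomal protein genes held a median of 11.6%. The 24 cells numbered 97 to 120 in their titles were shallower, with a median of 43006.5 UMIs and 1.58 reads per UMI, against medians of 125349 to 213704 UMIs in the 7 other blocks of numbers. In 6 cells with fewer than 5000 genes and more than 3 reads per UMI, few molecules were counted (2746 to 4708 genes, 6936 to 23618 UMIs). Which reads were counted is not given, so the high ratio cannot be read as repeated sequencing of the same molecules.

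**Figure D1:**
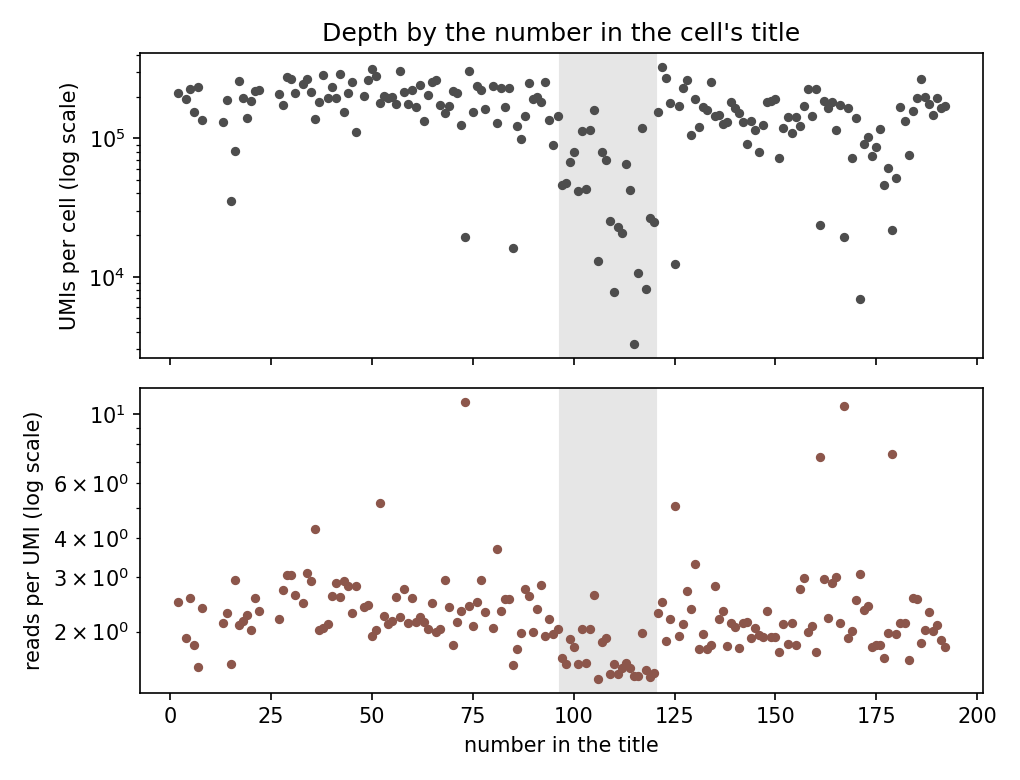
UMIs per cell (upper panel, log scale) and reads per UMI (lower panel, log scale) against the number in each cell's title, 1 point per cell, with numbers 97 to 120 shaded. The shaded cells had a median of 43006.5 UMIs and 1.58 reads per UMI, and single cells elsewhere reached up to 11.0 reads per UMI.

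After 9 days of organoid culture, genes of pancreatic duct cells and of simple epithelia were among the most abundant transcripts, and almost every cell carried them. The 15 duct genes of the list fixed beforehand together held 11634 CPM (11594 to 11674), with a median of 11722 per cell (quartiles 9661 and 13406). Krt7 and Krt19, keratins of duct epithelium, stood at 3524 and 1769 CPM and had a UMI in every cell. Spp1, a secreted phosphoprotein of duct cells, stood at 1678 CPM in every cell, but its highest level, 18552 CPM, was in a cell rich in fibroblast genes (described below). The median of the 6 such cells was 4758, against 1222 in the other cells with at least 40000 UMIs, so Spp1 is not specific to duct-like cells here. Ambp stood at 826 in 98.9% of cells. Sox9, a transcription factor of duct and progenitor cells, was lower, at 80.7 CPM (77.4 to 84.1) in 83.2% of cells, and Pdx1, a pancreas transcription factor, stood at 21.6 (19.9 to 23.4) in 78.2% of cells. When each cell was thinned to 40000 UMIs, which left out 18 shallower cells, at least 3 duct genes were detected in 100% of the thinned cells (97.7 to 100%), and also in 100% of all cells without thinning. Krt19 was detected in 100% of the thinned cells, Sox9 in 70.2% (62.5 to 77.1%) and Pdx1 in 52.2% (44.2 to 60.1%), against the unthinned 83.2% and 78.2%. The epithelial list held 10911 CPM (10872 to 10950), led by Krt8 (5350), Krt18 (2704), the membrane-cytoskeleton linker Ezr (771) and the tight junction gene Cldn7 (710).

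Among nuclear genes other than ribosomal protein genes, the most abundant transcript was Clu, a secreted chaperone induced by tissue injury, at 7763 CPM (7731 to 7796). It was followed by Krt8, Anxa2 (3974), S100a6 (3745), Actb (3690) and Krt7. Gm28437 (2990), an annotated pseudogene copy of mitochondrial sequence, came next, and its level is uncertain because reads can be shared with the mitochondrial original. The remaining members of the first 15 were Chd9 (2742), Krt18, Hsp90ab1 (2494), Eef2 (2233), Tmsb10 (2073), Ybx1 (1949), Krt19 and Atp5b (1733), each with a UMI in every cell. In GRCm38, Clu lies on chromosome 14 at 65968483 to 65981547, Krt8 on chromosome 15 at 101996698 to 102004482, Krt7 on chromosome 15 at 101411043 to 101430313, Krt19 on chromosome 11 at 100140810 to 100148665 and Spp1 on chromosome 5 at 104435118 to 104441050.

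Digestive enzyme transcripts, the products that define acinar cells in the tissue, were low in most cells and by far the highest in 1. The 27 acinar genes held 2558 CPM pooled over all cells (2539 to 2577), but 81.8% of these UMIs came from Acinar52. In that cell, 32.4% of 179841 UMIs (32.1 to 32.6%) belonged to the list, and 26 of its 27 genes had a UMI. Without that cell the pooled level was 469 CPM, and without Acinar55 as well, the next highest at 22543, it was 309. Acinar98 and Acinar155 stood at 11907 and 10116, while the median of all cells was 166.1 (quartiles 130.2 and 239). In Acinar98 most of this level was Zg16 (9082 CPM) and Sycn (1862). Of the enzyme genes described next, it held Ctrb1 at 628 CPM and no UMI of Prss2 or Cpa1. Ctrb1, which encodes chymotrypsinogen, stood at 85203 CPM in Acinar52 (83859 to 86563) and at a median of 87.5 over all cells. Prss2, a trypsinogen gene, stood at 54743 in Acinar52 and at a median of 9.52. The lipase cofactor Clps stood at 30388 and 11.2, and the carboxypeptidase Cpa1 at 26852 in Acinar52, with a UMI in only 37.4% of cells. In the same cell Krt7 was at 217 CPM (154.2 to 296), while the median of the other cells was 3343.

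Among transcription factors that maintain acinar identity, Ptf1a and Rbpjl were close to absent outside that cell. Ptf1a had 29 UMIs, all in Acinar52, so that 1 thinned cell had a UMI (0.621%, 0.0157 to 3.41%). Rbpjl, its partner in the same complex, was seen in 3 cells, with 95.7% of its UMIs in Acinar52. Bhlha15, which encodes the secretory cell factor Mist1, was low but spread, in 22 cells at 1.98 CPM (1.49 to 2.57), with 18.2% of its UMIs from Acinar52. Nr5a2, a nuclear receptor active in acinar cells and elsewhere in the gut, was higher, at 26.2 CPM (24.4 to 28.2) in 78.8% of cells. Ptf1a lies on chromosome 2 at 19445663 to 19447501, Bhlha15 on chromosome 5 at 144190286 to 144194441 and Ctrb1 on chromosome 8 at 111686519 to 111691010.

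At least 3 acinar and at least 3 duct genes were detected together in 72.7% of thinned cells (65.1 to 79.4%). Every thinned cell passed for duct genes, so this share equals that for acinar genes alone. The share was set by the depth and the number of genes asked for: it was 92.7% without thinning and 24.2% when 5 genes were asked for. The 6 cells rich in fibroblast genes, described below, are the nearest to a background here. Acinar188, which is among them, is an imperfect one, with Krt7 at 2658 CPM, Krt19 at 970 and the duct list without Spp1 at 6410, within the range of the other cells (from 2085). Acinar genes passed in 4 of those 6 (66.7%, 22.3 to 95.7%, median depth 169027 UMIs) and in 72.9% of the others (65.2 to 79.7%, median depth 171929 UMIs), so the low acinar share is not above this background. The duct list passed in 6 of 6 as well (100%, 54.1 to 100%), so the duct share of 100% is not above it either. The median duct level was 5482 CPM in the 6 cells and 11733 in the others, and without Spp1 it was 776 and 9705. The background for duct keratins was far below their level in the other cells: the median of Krt19 was 101.3 CPM in the 6 cells and 1493 in the others, and that of Krt7 was 159.8 and 3411. Nr5a2 was also above it, with a UMI in 0 of the 6 thinned cells and in 56.8% of the others (48.6 to 64.7%). For Sox9 the 6 cells could not decide this, because its median and its share of cells went opposite ways. The medians were 61.8 CPM in the 6 cells and 49.1 in the others. A Sox9 UMI was seen in 3 of the 6 thinned cells (11.8 to 88.2%) and in 70.97% of the others (63.1 to 77.97%). The thinned cells were also ordered by acinar level and divided into 4 bins of 40 or 41 cells, with a median acinar level of 100 CPM in the lowest bin and 312.5 in the highest. The median duct levels of the bins were 11725, 12012.5, 11562.5 and 11050. A single UMI is worth 25 CPM at this depth, so the bins below the highest, which end at 225 CPM, are ranges of a few UMIs. The highest bin runs from 250 to 324450 CPM and includes Acinar52. The bins are ranges of a score and not cell types.

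**Figure D2:**
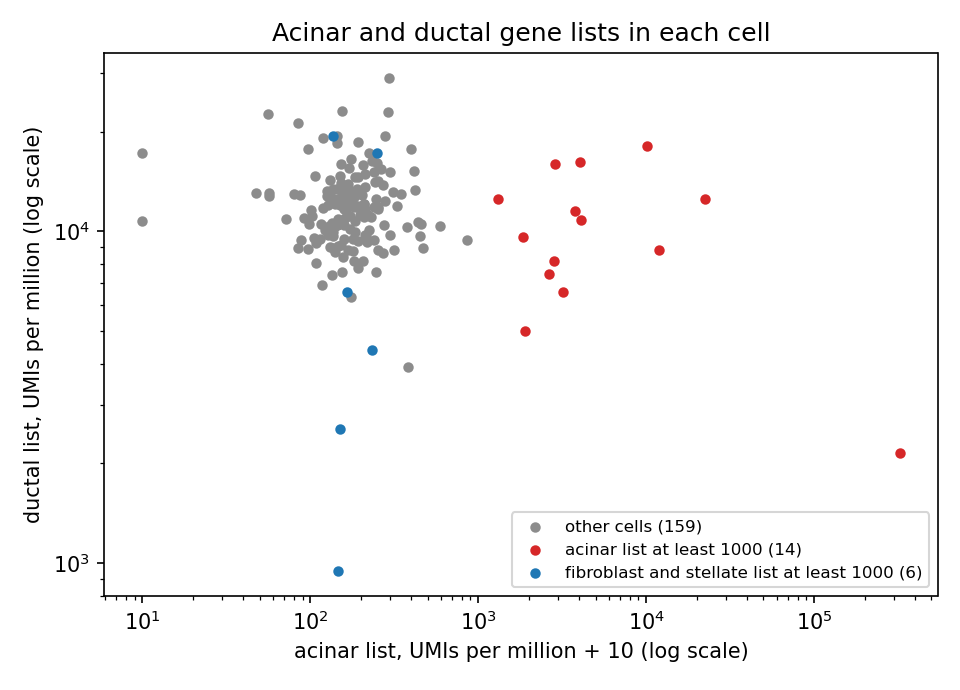
Acinar list against ductal list in each cell, both in CPM on log scales, with 10 added on the acinar axis so that cells at 0 can be drawn. Red points are the 14 cells with at least 1000 CPM of the acinar list, blue points the 6 cells with at least 1000 of the fibroblast and stellate list, and grey points all other cells. Of the red points, 6 are the cells with few molecules, which reach that level with 26 to 79 acinar UMIs. Acinar52 lies alone at the right, and the blue cells share the acinar range of the grey cells.

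Genes linked to metaplasia and injury were abundant in the population. The 20 genes of that list held 22903 CPM (22846 to 22959), and at least 3 of them were detected in every thinned cell, the 6 fibroblast-rich ones included. The median level was 7401 in those 6 and 22876 in the others, with Clu at 428 and 7055, Anxa2 at 1822 and 4066, Mmp7 at 41.2 and 1629, Lcn2 at 13.9 and 938, Onecut2 at 25.7 and 822 and Tff1 at 186.3 and 212. Clu, Anxa2, S100a6 and the matrix metalloproteinase Mmp7 (1606) were its highest members. Lcn2, an iron-binding acute phase protein, stood at 1343, and the transcription factor Onecut2 at 834 in 98.3% of cells. Tff1, a trefoil peptide of the stomach surface, was uneven, with a pooled level of 991 and a median cell at 216. Vim had a UMI in only 19 cells and Muc6 stood at 3.52 CPM. Lcn2, Onecut2, Tff1, Vim and Muc6 were chosen after their values were seen, as were Rbpjl, Nr5a2, Nkx6-1, Ddit3, Bnip3, Adm, Lgr5 and Axin2. Part of this list is shared with duct cells in general, and no uncultured acinar cell was measured beside these, so no change over the culture can be given.

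Regulators of pancreas development were detected at lower levels, with 489 CPM for the list (481 to 497) and at least 3 genes in 95.7% of thinned cells (91.2 to 98.2%) and 96.1% without thinning. Hnf4a (152.6), Hes1 (151.4), Foxa2 (64.9) and Gata6 (49.7) led it, while Nkx6-1 had a UMI in 7 cells. Targets of the mechanosensitive co-activator YAP varied more between cells. The list had a pooled level of 1848 CPM (1832 to 1864) and a median cell at 1095, with quartiles of 438 and 2519. Ankrd1 (944), Ccn2 (313), Ccn1 (223) and Tead1 (162.7) were its highest members.

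A fibroblast programme was carried by 6 cells. The 10 fibroblast and stellate genes held 267 CPM over all cells (261 to 273) and 4.30 without these 6. Acinar5, Acinar6, Acinar44, Acinar105, Acinar182 and Acinar188 each held between 3920 and 12414 CPM, against at most 274 in any other cell. The collagen genes Col1a2 (85.2 CPM), Col1a1 (82.7) and Col3a1 (29.2) and the receptor gene Pdgfrb (24.3) were its highest members, seen in 12, 20, 9 and 10 cells. The epithelial list was at 477 to 695 CPM in 5 of the 6 and at 3645 in Acinar188, against 4031 or more in every other cell. With thinning, 7 cells had at least 3 genes of this list (4.35%, 1.77 to 8.75%), and 4.47% did without thinning. The level of 1000 used to single out these cells was set after the data were examined.

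No group of endothelial, immune or Schwann cells was found. The endothelial list stood at 28.4 CPM (26.5 to 30.5) and was detected in 2 thinned cells and in 6.15% of cells without thinning, with Pecam1 (13.6), Eng (11.2), Plvap (2.30) and Esam (0.611) leading. Without the 6 fibroblast-rich cells the list fell by more than 1.5 times, to 17.5. The immune list stood at 6.79 (5.86 to 7.83) and the Schwann list at 14.4, each detected in 0 of the thinned cells, which allows a share of up to 1.86%. Without thinning, the immune list was detected in 4 cells (2.23%) and the Schwann list in 0. Only 4 of the 5 Schwann genes and 8 of the 10 immune genes had an entry. Asking for 3 genes is therefore a strict rule, most of all for the Schwann list. The immune list was led by Cd68 (2.37), Csf1r (2.08), Coro1a (1.01) and Fcer1g (0.791), and the Schwann list by S100b (12.5). Sst, Ppy, Cd3e, Tyrobp, Sox10, Sftpc and Umod had no entry under these symbols, so they were not analysed here. The endocrine list stood at 72.4 CPM (69.3 to 75.6), almost all of it insulin: Ins2 stood at 44.9 in 69.8% of cells and Ins1 at 20.5 in 63.1%. With equal weight per cell the list stood at 147.9, but 96.9 without Acinar171, a cell with few molecules (6936 UMIs) at 9227 CPM. It was detected in 11.8% of thinned cells (7.26 to 17.8%) and in 32.4% of cells without thinning. Iapp stood at 6.33 and Chga at 0.216, and Neurog3 had no UMI, which allows a level of up to 0.108 CPM. The off-tissue background list stood at 108.3 CPM (104.4 to 112.2), nearly all from Mbp (74.8 in 93.3% of cells) and Nphs1 (30.2 in 82.1%), and the next highest members, Snap25 and Gfap, stood at 1.51 and 0.755. Mbp was uneven between cells: it had 0 UMIs in 4 of the 6 fibroblast-rich cells, 1 in Acinar6 and 8 in Acinar188 (44.9 CPM, 19.4 to 88.4), against a median of about 65 CPM in other cells. The list was detected in 9 thinned cells (5.59%, 2.59 to 10.3%) and in 21.8% of cells without thinning.

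**Figure D3:**
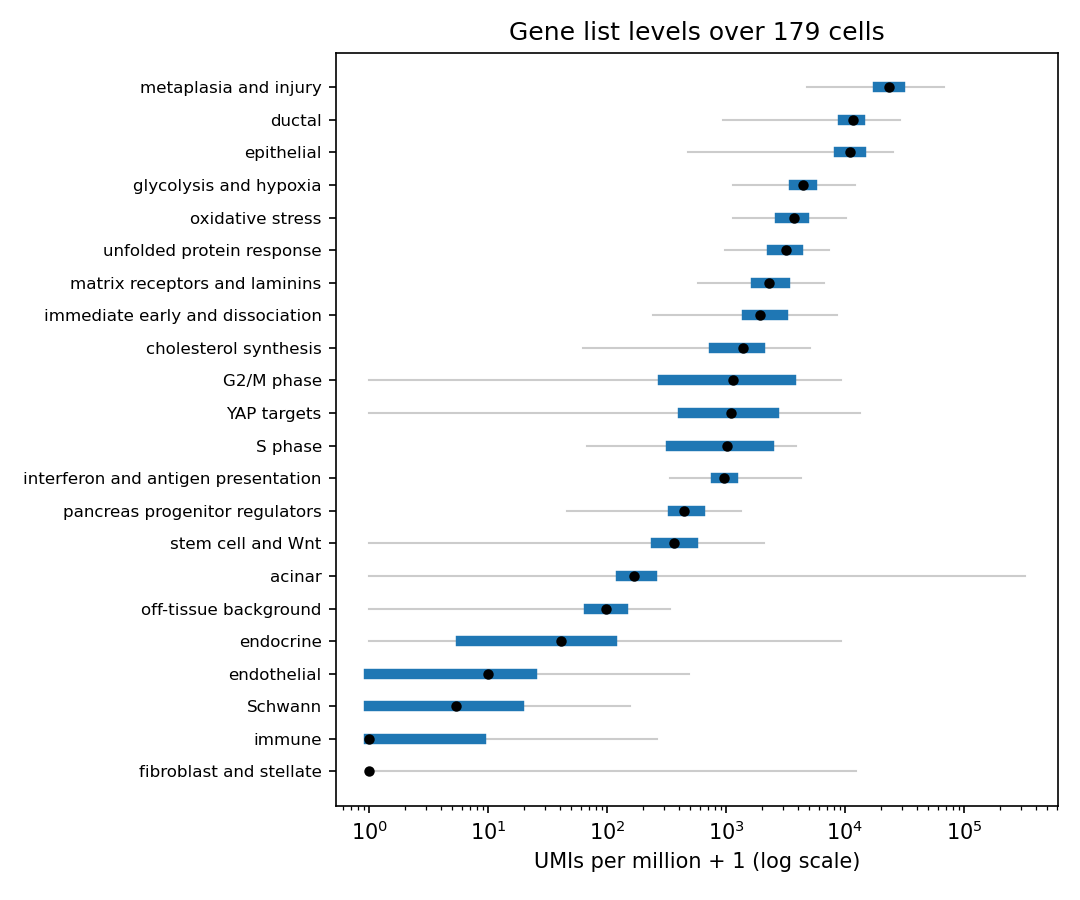
Level of each of the 22 gene lists over all cells, in CPM with 1 added, on a log scale. Dots are medians over cells, thick bars run between the quartiles and thin lines between the lowest and highest cell. The metaplasia and injury list had the highest median, and the acinar list, with a median of 166.1, reached 323630 in 1 cell.

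Cell cycle genes were detected in most cells and ranged widely between them. At least 3 G2/M genes were found in 95.7% of thinned cells (91.2 to 98.2%) and at least 3 S phase genes in 97.5% (93.8 to 99.3%), against 97.8% and 98.3% without thinning. The number of the 21 G2/M genes detected in a thinned cell had quartiles of 5 and 19. The G2/M list stood at 2472 CPM pooled (2454 to 2491), with a median cell at 1149 and quartiles of 293 and 3483. The S phase list stood at 1409 (1396 to 1423), with a median cell at 1019. Top2a (332), Ube2c (316), Stmn1 (277) and Cdk1 (197) led the G2/M list, and Rrm1 (206), Pcna (183.4), Mcm6 (135.5) and Mcm3 (121.8) the S phase list. The proliferation marker Mki67 stood at 167.04 CPM (162.3 to 171.9) and was detected in 65.2% of thinned cells (57.3 to 72.5%), and Stmn1, which binds tubulin, was detected in 93.8% (88.9 to 96.98%), against 74.9% and 94.97% without thinning. No phase was called for any cell, and 5 of the 6 fibroblast-rich cells also passed for 3 G2/M genes.

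**Figure D4:**
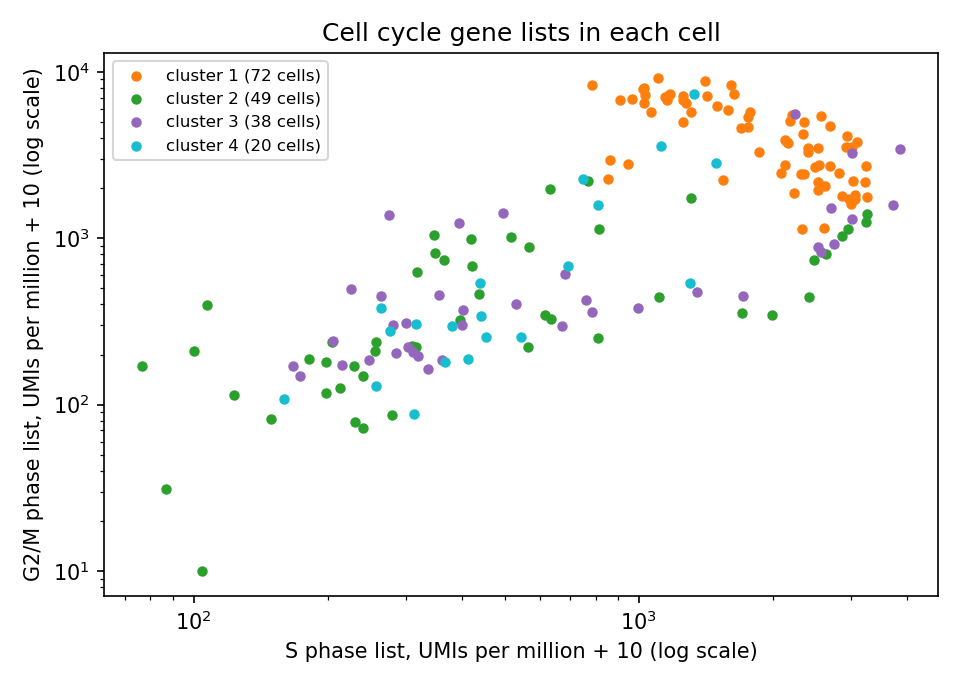
S phase list against G2/M phase list in each cell, in CPM with 10 added, on log scales, coloured by the 4 clusters. The 72 cells of cluster 1 lie in the upper right, with a median of 3842 CPM for the G2/M list, against medians of 313 to 403 in the other clusters.

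Stress and metabolic lists were present in nearly all cells. The unfolded protein response list held 3296 CPM (3275 to 3318), with the endoplasmic reticulum chaperones Hsp90b1 (1314), Hspa5 (802) and Calr (511) ahead of the transcription factor Atf4 (282), while Ddit3 stood at 20.02. Immediate early genes held 2375 (2357 to 2393), led by Junb (614), Ier3 (379), Fos (291) and Egr1 (254). Glycolysis and hypoxia genes held 4528 (4503 to 4553), led by Gapdh (912), Eno1 (677), Ldha (663) and Aldoa (650). The hypoxia-induced genes Bnip3 and Adm stood at 4.06 and 0.503, but they do not stand for the other members of the list. In mean UMIs per cell, Slc2a1 stood at 34.9, Car9 at 23.4, Ndrg1 at 10.8, Vegfa at 7.73 and Pdk1 at 6.93, against 0.631 for Bnip3. These members were also chosen after their values were seen. Oxidative stress genes held 3749 (3726 to 3772), led by Gsta4 (1270), Prdx1 (1171), Gpx2 (295) and Txnrd1 (270.5). Cholesterol synthesis genes held 1466 (1452 to 1481), with Hmgcs1 (280.5), Cyp51 (248) and Fdft1 (175.2) among the highest.

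Genes of cell adhesion to the surrounding matrix held 2553 CPM (2534 to 2571), led by Lama5 (384), Dag1 (378), Itga2 (290) and Itga3 (270), which encode a laminin chain, dystroglycan and a pair of integrin chains. Interferon and antigen presentation genes held 1042 (1030 to 1054), most of it from the class I genes H2-D1 (465), H2-K1 (258) and B2m (217), followed by Bst2 (32.1). The stem cell and Wnt list held 407 (400 to 415), and 327 of this was Prom1. Nes (37.7), Aldh1a1 (35.4) and Bmi1 (5.89) came next, and the Wnt target Lgr5 stood at 0.359 CPM in 9 cells and Axin2 at 0.575.

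Variation between cells beyond counting noise was largest for pancreatic enzymes and gastric surface genes, and rested on single cells. Of 13394 genes with a mean of at least 0.5 UMI per cell, the 20 with the largest relative excess variation were Prss2, Try5, Cpa1, Amy2a3, Amy2a5, Pnliprp1, Cela2a, Amy2a2, 2210010C04Rik, Gkn1, Clps, Ctrb1, Gkn2, Ctrl, Amy2a1, Amy2b, Reg1, Amy2a4, Klk1 and Try4. All 20 had over 50% of their UMIs in a single cell, 18 of them in Acinar52. Amylase genes and trypsinogen genes are near-identical copies of one another, so the split of UMIs within each family is uncertain. Gkn1 and Gkn2, which encode gastrokines of the stomach surface, had 68.2% and 78.9% of their UMIs in Acinar22. The excess squared coefficient of variation was 130.9 for Prss2 and 73.4 for Gkn1, and its median over genes was 0.319. Without Acinar52, 3 of the 20 stayed in the list (Gkn1, Gkn2 and Ctrb1). Of the others that then entered, those led by fibroblast-rich cells were Mgp, Igfbp5, Ank, Ptn, Col8a1, Acta2, Lpl, Cxcl14 and Col10a1. The rest were Muc5ac, Psca, Mucl3, Zg16, Ehhadh (81.4% of UMIs from Acinar60), 1700030N03Rik (55.7% from Acinar65), Triobp (63.7% from Acinar74) and Acta1 (71.7% from Acinar164).

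Clustering gave 4 clusters of 72, 49, 38 and 20 cells, or 40.2% (32.98 to 47.8%), 27.4% (20.99 to 34.5%), 21.2% (15.5 to 27.95%) and 11.2% (6.96 to 16.7%). They are given by number, because every cluster carried all 15 duct genes and the leading genes of none were duct genes. Cluster 1 was described by Ube2c, Plk1, Hist1h2ao, Cdc20 and Pif1, genes of cell division, with folds of 7.92 to 10.8 over the other cells. Cluster 2 was led by Pnliprp1, Prss2, Cpa1, Try5 and Cela2a, with 94.1% to 99.6% of their UMIs in it from Acinar52. Cluster 3 was led by Wfdc18 (fold 20.01), Krt17, Rgs5, 2610307P16Rik and Mcam, of whose UMIs in it 52.2% to 92.5% came from 6 cells, and 74.3% of those of Rgs5 from Acinar172. Its YAP target list stood at a median of 3135 CPM per cell, against 519 in cluster 2, 1140 in cluster 1 and 1666 in cluster 4. The immediate early and dissociation list was highest there too, with a median of 3338, against 1723, 1885 and 2043 in clusters 1, 2 and 4. Cluster 4 held the 6 fibroblast-rich cells, and its leading genes Mgp, Col1a2, Col1a1, Col8a1 and Igfbp5 had over 99% of their UMIs in the cluster from 6 cells. At resolution 1, which gave 10 clusters, those 6 cells formed a cluster of their own, a fibroblast-like cluster with all 10 markers detected. A simulated population with no groups was also split into 4 clusters by the same steps, so finding 4 clusters is no evidence of distinct cell types.

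The UMI and read tables ranked genes alike. Across 17752 genes with at least 20 pooled UMIs, Pearson's r between log2 CPM of UMIs and log2 CPM of reads was 0.994 and Spearman's rho 0.993, across genes, which are not independent replicates. The median gene had 2.21 reads per UMI (quartiles 2.05 and 2.37). The highest ratios among genes with at least 200 UMIs were those of Prss2 (10.5), Klhl9 (10.3), the pseudogene Gm29216 (9.66), Amy2a3 (9.40) and Cela2a (8.49). For Prss2, Amy2a3 and Cela2a these values describe Acinar52, which holds 95.6%, 95.6% and 98.1% of their UMIs. The lowest were those of Gm3787 (1.01), Gm15745 (1.01), Gm5244 (1.02), Gm9550 (1.02) and Gm4750 (1.02), predicted genes of which 4 are pseudogenes. The acinar list weighed 3.00 times more when reads were used, at 7685 CPM of reads. This came mostly from Acinar52, with 5.17 reads per UMI: without it the list weighed 1.21 times more, and in cells below 1000 CPM of the list 0.940 times.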

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

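The alternatives that left out Acinar52 alone or with Acinar55, left out the 6 fibroblast-rich cells, asked for 5000 genes or used 2 rounds of the cluster search were chosen after seeing the data. Levels in CPM are given for the acinar, ductal, fibroblast and G2/M lists in that order. They were 7685, 13711, 307 and 2318 with reads in place of UMIs, 2384, 11927, 244 and 2223 with equal weight per cell, and 2907, 13222, 303 and 2810 without mitochondrial and ribosomal protein genes in the total, which raises every list by construction. Title numbers up to 96, which hold Acinar52, gave 4096, 11279 and 259 for the first 3 lists, and numbers from 97 gave 414, 12129, 278 and 2496. Without Acinar52 the acinar and ductal lists stood at 469 and 11696, and without Acinar55 too the acinar list stood at 309. Without the 6 fibroblast-rich cells the lists stood at 2653, 11741, 4.30 and 2497. A minimum total of 5000 UMIs and a mitochondrial limit of 20% changed no list beyond its counting interval. The minimum left out only Acinar115, with 3258 UMIs, so it could hardly move a pooled level. Having no minimum left the same cells and could change nothing. The endocrine list rose to 147.9 with equal weight per cell and to 96.9 without Acinar171, which was left out after seeing the data, and the endothelial list fell to 17.5 without the fibroblast-rich cells. Of 284 values of the other results under these settings, 40.5% moved beyond the counting interval. The cause of each shift was not tested unless stated.

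The share of cells with the acinar list, alone or with the ductal list, was 40.2% at 20000 UMIs per cell, 92.7% without thinning, 93.8% with 2 genes asked for and 24.2% with 5, so it follows the rule and the depth. The S phase share was 90.5%, and the G2/M share 84.02%, at 20000 UMIs, 99.4% for both with 2 genes, and 88.8% and 82.6% with 5. The ductal share stayed at 100% in every setting run. Of the 20 variable genes, 0 were shared with the list made with no minimum mean and 3 with the list made without Acinar52, while 19 or 20 were shared under the other settings. Clusters numbered 10 at resolution 1 and 4 to 6 elsewhere, with adjusted Rand indices to the reported clusters down to 0.443. The 6 fibroblast-rich cells stayed in 1 cluster in each setting run, but not always alone. That cluster held 20 cells in the main setting, 42 with 3000 variable genes and 21 without the cell cycle lists, and only the 6 in the other settings. No paired analysis was possible because there is 1 group.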

Other observations

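All tests in this part were chosen only after the results were seen, except the 2 on reads assigned to other barcodes. The genes and cells named here were also chosen after their values were seen. A few cells carried genes of the stomach surface at very high levels together with acinar list genes. Gkn1 and Gkn2, which encode gastrokines, stood at 27465 CPM (26781 to 28162) and 20760 CPM in Acinar22 and at 42081 and 17075 CPM in Acinar98, against medians of 27.5 and 9.39 in the other cells. Tff1 stood at 30725 and 47145 CPM in these cells and Psca at 12441 and 26554 CPM. In Acinar55 and Acinar175 the gastric mucin Muc5ac was high instead of the gastrokines, at 10579 and 8933 CPM, with Gkn1 at 15.1 and 22.9 CPM. Tff1 stood at 15693 and 6238 CPM there, above Muc5ac in Acinar55 and below it in Acinar175. Ctrb1 stood at 1202, 628, 19788 and 1193 CPM in Acinar22, Acinar98, Acinar55 and Acinar175, and most of the acinar list of Acinar98 was Zg16, at 9082 CPM. In Acinar22 Sycn stood above Ctrb1, at 1507 CPM, with Prss2 at 8.97 and Cpa1 at 4.48. Duct keratins were kept in these cells, with Krt19 at 3453 to 4086 CPM, except that Krt7 stood at 251 CPM in Acinar98.

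Acinar71 stood apart by the interferon-induced gene Isg15. Isg15, a ubiquitin-like modifier, stood at 932 CPM (807 to 1071), against a median of 0 in the other cells, and 76.8% of all its UMIs came from this cell. Irf7 stood at 585 CPM there, with 44.96% of its UMIs, but also at 368 CPM in Acinar22. Acinar155 held Ctrb1 at 9670 CPM together with the prolactin family gene Prl2c2 at 9155 CPM, against medians of 87.4 and 11.6 in the other cells.

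Most cells held a few acinar list UMIs, with a median of 28 in cells below 1000 CPM, and no biological explanation beyond transcription was tested. Reads of Acinar52 assigned to other barcodes should be seen about once each. The reads per UMI of the acinar list were 0.940 times those of all other genes in the same cells. This argues against such reads only if every counted read carried a UMI, which is not stated. Some reads (0.332%) fell where no UMI was counted. Transcription of the list as a whole in the epithelial cells themselves is argued against by the 6 fibroblast-rich cells. Their median level was 0.881 times that of the others (single cells 0.751 to 1.43). Their median Ctrb1 was 99.2 CPM, against 86.2 in the others with at least 40000 UMIs. This does not cover Nr5a2, a list member that is no enzyme, at 26.3 CPM in cells below 1000 CPM. Nr5a2 had no UMI in the 6 cells but was detected in 56.8% of the other thinned cells. RNA of Acinar52 alone is argued against too: UMIs of 16 other acinar genes over those of Ctrb1 stood at 0.249 (0.233 to 0.265) of the ratio in Acinar52, with single genes from 0.0929 for Spink1 to 6.46 for Cela1 and Prss2, tried first, at 0.225, although an earlier test, later left out, had found Ctrb1 at 49.4% of acinar UMIs against 26.3% in Acinar52, within its bound of 2 times. Free RNA of mixed source in a fixed amount per well stays open: acinar UMIs rose 3.18 times from the shallowest to the deepest cells where depth rose 5.29 times, and 1.762 times where it rose 2.79 times without title numbers 97 to 120, a restriction made after the ratio over all cells had gone against it.

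Insulin UMIs were seen without an endocrine cell, with a median of 5 per cell and at most 58. The 6 fibroblast-rich cells held them too, with medians of 20.6 CPM for Ins1 and 31.8 for Ins2. The medians of the others with at least 40000 UMIs were 8.82 and 25.3, so their insulin levels were not above this background. At least 3 endocrine genes were detected in 0 of the 6 thinned cells (0 to 45.9%) and in 12.3% of the others. The reads per UMI of Ins1 and Ins2 were 0.929 times those of all other genes. With the same limit on which reads were counted, this argues against reads assigned to other barcodes only if every read carried a UMI. A fixed amount of free RNA stays open, since the ratio of deepest to shallowest cells was 2.5 over all cells, against it, and 1.4 without title numbers 97 to 120, for it, at depth ratios of 5.29 and 2.79. No biological explanation was tested.

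Both the acinar list and Gkn1, Gkn2 and Muc5ac together reached 1000 CPM in 8 cells. Of these, 4 were weighed and 4, with 12442 to 23618 UMIs, were left out by a limit of 5000 genes set after the data were seen. The 4 left out are among the 6 wells with few molecules, where few UMIs make up 1000 CPM, so they are no clear case of both programmes. In those 6 wells Tff1 also stood high, at a median of 5313 CPM against 213 in the other cells. RNA from Acinar52 or a cell like it is argued against, since the ratio of Prss2 to Ctrb1 was at most 0.0748 of that in Acinar52, and at most 0.271 in the 4 left out. A first test, the cosine similarity of acinar profiles, lay between 0.0732 and 0.746 and decided nothing. A pair of cells in 1 well cannot be told apart from a single cell with both sets of genes. Total UMIs were a median of 0.867 times that of all cells, with a range of 0.289 to 1.35 (from 0.0753 with the 4 left out). The acinar level rested mostly on Zg16 and Sycn in Acinar98, Sycn and Ctrb1 in Acinar22, and Ctrb1 in Acinar55 and Acinar175. These levels therefore do not show a whole acinar programme, and no biological explanation was tested.

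The 6 wells with few molecules, below 5000 genes and above 3 reads per UMI, held 26 to 79 acinar UMIs, against a median of 30 in the other cells, and 5 to 57 insulin UMIs, against 4. The other cells below 5000 genes were Acinar106, Acinar110, Acinar115, Acinar116 and Acinar118, with at most 1.57 reads per UMI. They held at most 390 CPM of the acinar list and 0 insulin UMIs, so not all wells with few genes were alike. In title numbers 97 to 120, 15 of 24 cells had under 60000 UMIs. Xist had a UMI in 94.97% of cells, and of the Y-linked genes Uty stood at 4.67 CPM in 44.7% of cells, Kdm5d at 0.216 and Eif2s3y at 0.0359, so the Uty counts are doubtful as a sign of sex.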
